A study of Mus musculus with 12 samples.

How the data were processed

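RNA was extracted with a column kit and 1.0 µg of total RNA per library went into a NEBNext Ultra RNA kit for Illumina sequencing, per the labels' protocols, which do not state whether strand was kept. The 12 libraries fall into 6 groups of 2, each with a preparation 1 and a preparation 2, per the labels. The labels name 2 ways of delivering the mRNA, a transfection reagent and lipid nanoparticles, without saying which was used for which library, and give no time of treatment for the mRNA groups; vesicles were incubated for 24 h.

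The values used are gene counts as the authors deposited them. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm39, and per the file headers, uniquely mapped reads were counted with featureCounts (Subread 2.0.1) in paired-end mode over exons summed by gene, without a strand option, on the Ensembl release 103 annotation. The same settings stood in the headers of all 12 files. Counting uniquely mapped reads lowers genes with close copies, and counting without strand lets a gene and its antisense partner share reads, so such genes are given as uncertain. No trimming or HISAT2 version is given in the sources used here. The files hold 53647 genes by Ensembl identifier with coordinates; symbols came from a table of gene names, which matched 52093 of them, and 19162 of the 19228 genes with 10 or more counts in all. Coordinates are those of the files. Total counts per library were 14.1 to 26.0 M, 17174 to 18661 genes had a count, and mitochondrial genes took 1.17 to 2.41% of counts. Intervals and floors cover counting error only, with 3 counts as the floor.

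Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on all 12 libraries with 1 mean per group, TMM factors, filterByExpr by group (14863 genes) and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 3.05%. The 3 comparisons were uniSTING against Mock mRNA in each labelled cell line and EXOuniSTING against EXOmock; 2 further contrasts tested differences of responses. Means ± SD are of CPM over deposited totals, and standard errors come from the fold change and its F statistic. All of these, and 24 gene lists, were fixed before the data were examined.

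Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists with 3 or more tested members. Of these, 12, 5 and 4 lists were called in the 3 comparisons in the order given, and 4, 0 and 2 with an estimated correlation. A call lost in that setting does not by itself show that the members were correlated. Under the DC2.4 label with mRNA, the estimate for replication-dependent histone genes was -0.051, below the preset value, and their call was still lost. Overlaps of calls were tested with 2-sided Fisher's exact tests. Genes named were, per comparison, the 6 largest rises and 6 largest falls past the threshold, in the same direction in every library, with at least 5 CPM in the higher group, leaving out unnamed models, pseudogenes, antisense and mitochondrial genes; the 9 fixed genes Ifnb1, Cxcl10, Ifit1, Tmem173, Tbk1, Irf3, Tnf, Il6 and Wnt2b; and for each list discussed the members with the smallest adjusted p. For differences of responses the 6 genes with the smallest adjusted p in each direction were taken. Cell markers were read from the same fixed lists. Some genes that these rules pick and 1 gene list are not reported here.

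The procedure was tested on simulated counts drawn from the real means, dispersions and totals, with 100 genes changed 1.5-fold and 100 changed 3-fold per comparison. It recovered 71, 80 and 76% of the 1.5-fold and 94, 95 and 90% of the 3-fold changes. The order is the libraries labelled DC2.4 given mRNA, those labelled 4T1 and the vesicle-treated ones (14610, 14598 and 14624 genes). Of the calls, 11.8, 6.42 and 3.49% were false, the first 2 above the threshold of 0.05. A list shifted on purpose was called each time and 0 of 21 others. The simulation changed 200 genes, while 41.7, 28.3 and 16.1% of genes were called in the data. It also drew its spread from these libraries, so it does not give the share of false calls in the data.

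Replicates were compared by the variance of counts over that of counting and by a chi-square per gene. Exonic lengths came from the files; mRNA lengths and GC content of principal transcripts came from GENCODE M21, an annotation of an earlier mouse assembly used for lengths alone. Alternatives were DESeq2 1.42.0 and its size factors, upper-quartile factors, no filter on low counts, 1 CPM in 4 libraries, limma-voom, only the libraries compared, the preparation number as a block, a 2-fold minimum and leaving out each library. Removal of the length trend and fold sizes within 1 preparation were added after the data were examined. Tables were made with Python 3.11.15 and figures with matplotlib 3.10.9.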

Results

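Messenger RNA of mouse cells was measured by RNA sequencing in 12 libraries that the labels place in 6 groups of 2. The cell lines named are DC2.4, an immortalized mouse dendritic cell line, and 4T1, a mouse breast cancer line of epithelial origin. Cells of both lines received mRNA encoding uniSTING, which the series title describes as a mimic of STING, the adaptor that signals through the kinase TBK1 and the factor IRF3 to type I interferon. Controls received mRNA encoding the fluorescent protein EGFP and are called Mock. In a further experiment, DC2.4 cells were incubated for 24 h with extracellular vesicles from 4T1 cells that had been given uniSTING or Mock mRNA, called EXOuniSTING and EXOmock. Each group held 1 library of preparation 1 and 1 of preparation 2. Total counts per library lay between 14.1 and 26.0 M, and each preparation 2 library was 1.26 to 1.42 times deeper than its preparation 1 partner. A floor of 3 counts corresponded to 0.115 to 0.213 counts per M of the library total (CPM), which covers counting error only. The labels do not say that preparations came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

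The marker genes of the libraries went against their cell line labels in both mRNA-treated lines. In the 4 libraries labelled DC2.4 and given mRNA, the epithelial adhesion gene Epcam stood at 301 ± 16.6 CPM (SD, n = 4) and the keratin gene Krt8 at 1290 ± 19.0 CPM, while Ptprc, which encodes the pan-leukocyte antigen CD45, had 0 to 19 counts and the myeloid transcription factor gene Spi1 had 1 to 5. In the 4 libraries labelled 4T1, Ptprc stood at 318 ± 7.88 CPM and Spi1 at 188 ± 2.97 CPM, against 0 to 5 counts of Epcam and 0 to 15 of Krt8. The 4 vesicle-treated libraries labelled DC2.4 held Ptprc at 306 ± 3.91 CPM and Spi1 at 190 ± 12.1 CPM. Over the 20 fixed epithelial markers, the summed level was 6090 ± 156 CPM in the libraries labelled DC2.4 and given mRNA, 167 ± 2.06 CPM in those labelled 4T1 and 143 ± 6.95 CPM in the vesicle-treated ones. The sums of the 25 leukocyte markers were 189 ± 20.3, 9880 ± 128 and 14600 ± 1510 CPM in the same order. St14 alone held most of the low epithelial sums, at 161 and 163 CPM in Mock and uniSTING labelled 4T1 and 132 and 142 CPM in EXOmock and EXOuniSTING. Lcp1 held 114 and 136 CPM of the low leukocyte sums in Mock and uniSTING labelled DC2.4. The vesicle-treated leukocyte sums were 15800 and 15900 CPM in EXOmock and 13700 and 12900 CPM in EXOuniSTING, so their SD spans 2 groups. The first principal component held 94.6% of the variance and set the 4 libraries labelled DC2.4 and given mRNA apart from the other 8. Groups are named below by their labels throughout, and a direction stated for a cell line is a direction for the libraries that carry its label.

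**Figure D1:**
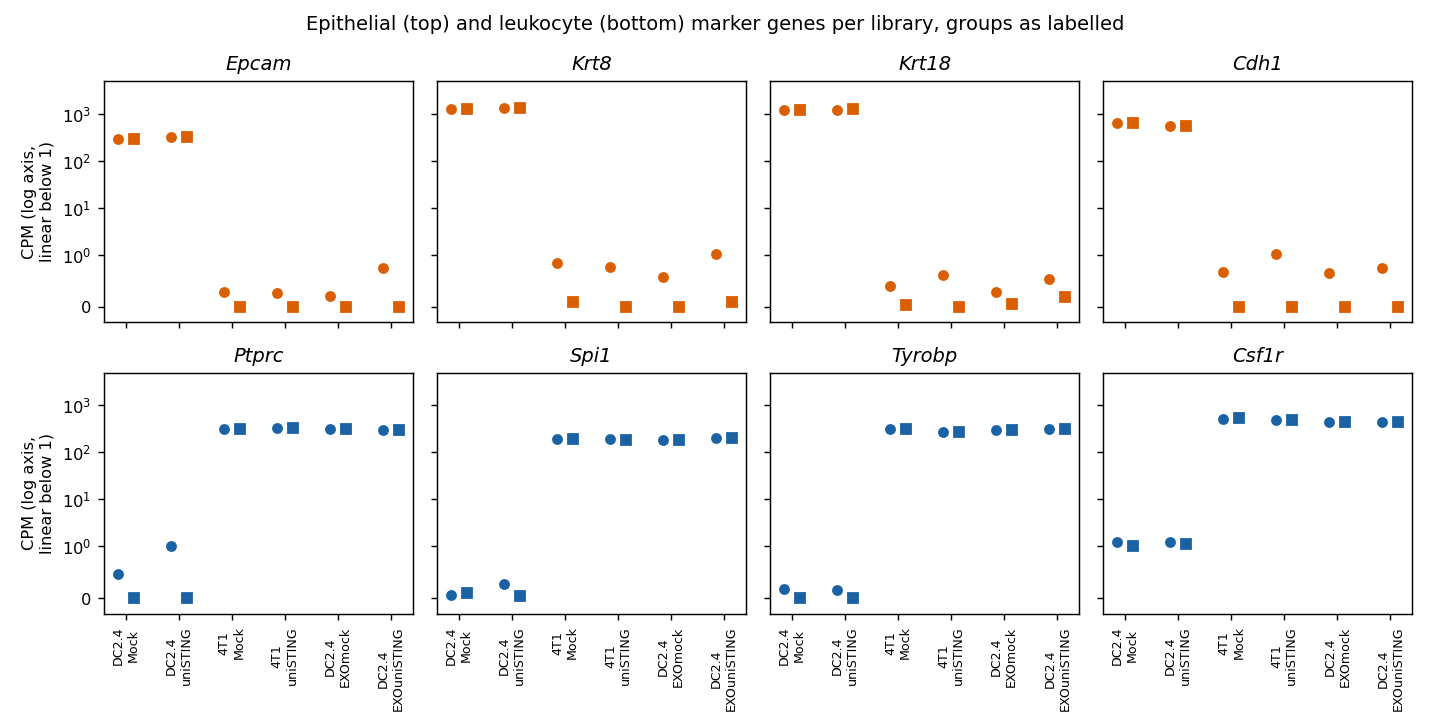
CPM of 4 epithelial markers (top) and 4 leukocyte markers (bottom) in each of the 12 libraries, on an axis that is logarithmic above 1 and linear below it; circles are preparation 1 and squares preparation 2. Epcam stood at 301 CPM in the 4 libraries labelled DC2.4 and given mRNA, and Ptprc at 318 CPM in the 4 labelled 4T1.

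Libraries of one group differed by little more than counting noise. The median variance per gene was 1.45 to 1.54 times that of counting within groups and 3.81 to 12.93 times between treated and control libraries. Among genes over 10000 counts, the variation beyond that of genes with intermediate counts was 0.35 to 0.62% within groups. The genes with intermediate counts themselves varied more than counting, so these percentages understate the variation beyond counting. The chi-square per gene within groups was 2.18 to 2.77, more than counting alone would give. It does not decide whether a pair was 1 library sequenced again, since reads carried over into preparation 1, left open below, would also raise it. Nor does it show that the libraries came from separate cultures or RNA. Because so small a spread lets very small changes pass the test, each total of called genes stands beside the count of at least 2-fold. Transcripts typical of other tissues were present in each of the 6 preparation 1 libraries and at 0 in each of preparation 2, a choice of genes made after their values were seen: the insulin gene Ins2 had 171 to 2117 counts in preparation 1 and the lung surfactant gene Sftpc 421 to 729.

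The first comparison asked how uniSTING mRNA changed the libraries labelled DC2.4, in particular their type I interferon response. Interferon-stimulated genes rose as a group: of 45 tested members, 40 rose (23 of them at least 2-fold), 2 fell and 3 did not pass, and the same 40 and 2 were counted adjusted over the list alone. The largest rise among genes of 5 CPM or more was that of Ifi44, an interferon-induced gene (ENSMUSG00000028037, GRCm39 chromosome 3, 151436559 to 151455597), from 1.29 ± 0.0309 to 9.48 ± 0.418 CPM (SD, n = 2; log2 fold change 2.89, SE 0.29, edgeR adjusted p = 3.72e-06). Cxcl10, which encodes a chemokine that recruits T cells (ENSMUSG00000034855, chromosome 5, 92494497 to 92496748), rose from 1.29 ± 0.353 to 6.59 ± 0.131 CPM (log2 fold change 2.38, SE 0.42, adjusted p = 0.000385). Ifit1, an interferon-induced protein that binds foreign RNA, rose by 2.20 on the log2 scale, the transcription factor gene Irf7 by 2.12 and the antiviral gene Rsad2 by 2.02. The more abundant members Ifitm3 (131 ± 3.50 against 85.6 ± 5.02 CPM) and Bst2 (73.9 ± 1.2 against 44.2 ± 3.63 CPM) rose by 0.64 and 0.75. The list's median log2 fold change was 1.01, and it stood apart from other genes by camera (adjusted p = 3.07e-14) and with an estimated correlation (adjusted p = 0.00186).

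Other immune genes of this comparison moved less evenly. Of 22 genes of MHC class I presentation, 9 rose and 2 fell, also adjusted over the list alone, among them the class I heavy chain gene H2-K1 (log2 fold change 0.43) and the proteasome activator gene Psme2 (0.71). Camera called the list (adjusted p = 0.0042), a call lost with an estimated correlation (adjusted p = 0.0749). The 37 NF-kB targets went both ways, with 12 higher and 7 lower (12 and 8 adjusted over the list alone), such as Ptgs2 at 0.48 and Csf1 at -0.62, and the list was not called (adjusted p = 0.568). Tnf rose from 5 to 25 summed counts (log2 fold change 2.14, adjusted p = 0.00222). The interferon gene Ifnb1 (ENSMUSG00000048806, chromosome 4, 88440262 to 88441011) was too low to test, with 12 summed counts against 3 (ratio 3.60, 95% counting interval 0.972 to 19.9), and none of the 20 interferon genes on the list could be tested, so a change in them was not detectable at this depth. Among the pathway's own genes, Tbk1 rose by 0.15 (adjusted p = 0.0349), while Tmem173, which encodes STING, stood at 0.09 (adjusted p = 0.455) and Irf3 at 0.04 (adjusted p = 0.7). The sequence of the uniSTING mRNA is not given in the sources used here, so any of its reads counted under these genes were not told apart from the cells' own.

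Metabolic genes rose in the same libraries. Of 25 glycolysis and hypoxia genes, 21 rose (6 at least 2-fold) and 1 fell, also adjusted over the list alone (camera adjusted p = 2.22e-20, and 0.0193 with an estimated correlation). Ldha, which encodes lactate dehydrogenase (ENSMUSG00000063229, chromosome 7, 46490899 to 46505051), rose from 1910 ± 13.3 to 2850 ± 12.3 CPM (log2 fold change 0.60, SE 0.01, adjusted p = 2.05e-12), Pgk1 by 0.61 and the hypoxia-responsive gene Ndrg1 by 0.96. Of 22 cholesterol synthesis genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone), with Msmo1 at 0.76, Idi1 at 0.86 and Mvd at 0.99 (camera adjusted p = 3.39e-14, and 0.00534 with an estimated correlation). Ribosomal protein genes rose in 37 of 39 cases, also adjusted over the list alone, with a median of 0.32 and Rpl19 at 0.46 (camera adjusted p = 1.43e-34, and 0.00732 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 16 of 22 cases, also adjusted over the list alone (median 0.23, camera adjusted p = 4.54e-10, but adjusted p = 0.0549 with an estimated correlation). With the trend by gene length given below removed, the ribosomal protein and oxidative phosphorylation medians were 0.17 and 0.10. Genes matched to these 2 lists on mRNA length and mean count had medians of 0.28 and 0.20. At 2-fold, 0 members of the cholesterol, ribosomal protein, oxidative phosphorylation and MHC class I lists were called in either direction.

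Some matrix and Wnt pathway genes and most histone genes fell. Of 28 TGF-beta and matrix genes, 11 fell and 1 rose, also adjusted over the list alone, led by the fibronectin gene Fn1 at -1.18 and by Thbs1 at -0.40. Of 32 Wnt pathway genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone), among them the beta-catenin gene Ctnnb1 at -0.25 and Apc at -0.61. Cell cycle genes went both ways, 16 lower and 11 higher, also adjusted over the list alone, with the proliferation marker Mki67 at -0.93. Of 14 replication-dependent histone genes, 11 fell, each at least 2-fold (12 adjusted over the list alone), such as Hist1h1e at -1.63, from a low level (7.92 ± 0.539 to 2.52 ± 0.558 CPM). Mitochondrially encoded mRNAs fell in 9 of 12 cases, also adjusted over the list alone, with mt-Nd4 at -0.29. Camera called these 5 lists (adjusted p = 0.000891, 0.00592, 0.0495, 0.00592 and 0.000289), and none of the 5 calls held with an estimated correlation (adjusted p = 0.303, 0.104, 0.209, 0.0698 and 0.295). Of 20 epithelial markers, 4 rose and 1 fell, also adjusted over the list alone, with the keratin gene Krt19 at 1.00 (camera adjusted p = 0.0157, and 0.594 with an estimated correlation). Of 24 leukocyte markers, 5 rose and 1 fell (4 and 1 adjusted over the list alone), with the actin-bundling gene Lcp1 at 0.28 and the integrin gene Itgb2 at -0.21, and the list was not called (adjusted p = 0.353).

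The largest falls among genes of 5 CPM or more were those of the histone genes Hist1h3e (log2 fold change -3.41, 23 against 230 summed counts) and Hist1h1e, of Masp1 (-1.39), and of 3 genes that encode very large proteins. Plec, which encodes the cytoskeletal linker plectin (ENSMUSG00000022565, chromosome 15, 76055174 to 76116774), fell from 293 ± 0.364 to 101 ± 4.05 CPM (log2 fold change -1.52, SE 0.03, adjusted p = 5.81e-13), the receptor gene Lrp1 by 1.47 and the perlecan gene Hspg2 by 1.46. Across 10548 genes, which are not independent replicates, the log2 fold change fell with exonic length (Spearman's rho -0.42). The median was 0.26 in the shortest 10% of genes and -0.26 in the longest, against 0.04 and -0.03 in the libraries labelled 4T1 (rho -0.12) and 0.03 and -0.06 in the vesicle-treated ones (rho -0.13). Ribosomal protein genes are short, with a median mRNA of 0.914 kb, and genes matched to them on mRNA length and mean count had a median of 0.28 beside their own 0.32. Genes matched to those of oxidative phosphorylation (median mRNA 1.3 kb) had 0.20 beside their 0.23. The trend removed next was that with exonic length, with medians of 2.01 and 2.43 kb for these 2 lists, not that with mRNA length. With the length trend removed, a step added after the trend was seen, camera no longer called MHC class I genes (median 0.14 before and 0.06 after, adjusted p = 0.109) or epithelial markers (0.13 and 0.05, adjusted p = 0.392). The medians went from 0.23 to 0.10 for oxidative phosphorylation, from 0.32 to 0.17 for ribosomal protein genes, from -0.23 to -0.17 for the Wnt pathway, from -0.19 to -0.13 for matrix genes, from -0.04 to -0.05 for the cell cycle and from -0.16 to -0.41 for mitochondrially encoded mRNAs, and these lists stayed called at the preset correlation. With an estimated correlation, only the ribosomal protein (adjusted p = 0.00101) and mitochondrially encoded genes (adjusted p = 0.0299) among these 6 were called. The median of the replication-dependent histone genes went from -1.79 to -2.11. Camera called that list at the preset (adjusted p = 0.000178) and at an estimated correlation (adjusted p = 0.0233).

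In all, edgeR's quasi-likelihood test called 3094 genes higher and 3102 lower of 14863 tested (Benjamini-Hochberg adjusted p below 0.05), 325 and 217 of them at least 2-fold. By size alone, 75 genes of 5 CPM or more were at least 2-fold higher and 40 lower. Sumo2, among the 6 largest rises (947 and 2330 counts against 331 and 393), histone, Ifit, MHC class I and ribosomal protein genes have close copies, so their values are uncertain where reads were split among copies.

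**Figure D2:**
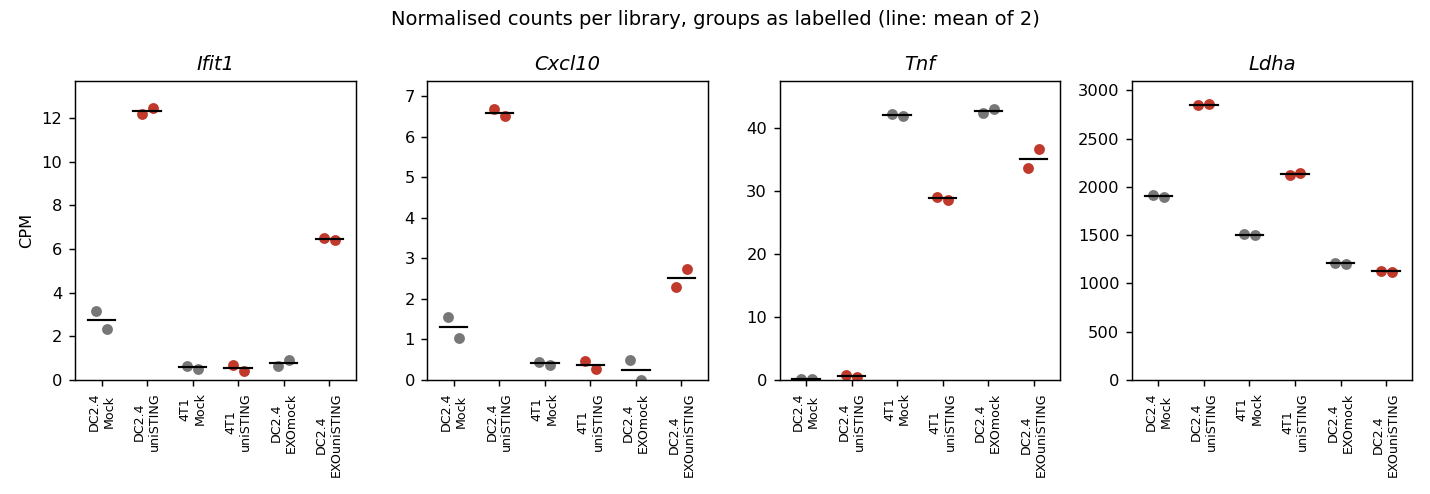
CPM of Ifit1, Cxcl10, Tnf and Ldha in each library (points; treated red, control grey) with the mean of 2 libraries per group (line), groups as labelled. Ifit1 rose from 2.73 to 12.3 CPM in the libraries labelled DC2.4 given mRNA and from 0.775 to 6.45 CPM in the vesicle-treated ones, and stood at 0.565 and 0.543 CPM in the libraries labelled 4T1.

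The second comparison asked the same of the libraries labelled 4T1. Their interferon-stimulated genes moved little: 9 of 45 rose (3 at least 2-fold), 4 fell (1 at least 2-fold) and 32 did not pass, or 11 and 4 adjusted over the list alone, with a median of 0.06 and a mean of 0.25 (camera adjusted p = 0.235). Rsad2 rose by 1.72 from a low level (0.462 ± 0.0201 to 1.58 ± 0.28 CPM), Ifi204 by 0.94 and Ifitm3 by 0.43, while Samhd1 fell by 0.27. Ifit1 stood at 0.565 ± 0.0705 CPM in Mock and 0.543 ± 0.169 CPM in uniSTING (adjusted p = 0.897), Cxcl10 had 16 summed counts against 17 (adjusted p = 0.889), and Ifnb1 had 0 counts in all 4 libraries. Tmem173 (log2 fold change 0.03, adjusted p = 0.837), Tbk1 (-0.01, adjusted p = 0.925) and Irf3 (0.09, adjusted p = 0.355) did not pass the test.

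Part of the NF-kB targets fell in these libraries. Of 37 tested, 18 fell, 1 rose and 18 did not pass, with the same 18 and 1 adjusted over the list alone, with a median of -0.25, or -0.22 with 5 members that had a group at 0 set to their bound. Nfkbia, which encodes the inhibitor of NF-kB and is itself a target (ENSMUSG00000021025, chromosome 12, 55536195 to 55539432), fell from 86.5 ± 2.71 to 56.8 ± 1.88 CPM (log2 fold change -0.64, SE 0.06, adjusted p = 2.05e-06), Tnfaip3 fell by 0.54, Nfkb2 by 0.40 and Tnf by 0.57. No member changed at least 2-fold. Camera called the list (adjusted p = 2.56e-05), a call lost with an estimated correlation (adjusted p = 0.0956). Among leukocyte markers, 9 of 24 fell and 4 rose (10 and 4 adjusted over the list alone), with the lysosomal gene Cd68 at -0.40 (median -0.10, mean 0.03; camera adjusted p = 0.0409, and 0.573 with an estimated correlation).

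Cell cycle genes rose in 19 of 35 cases and fell in 2 (21 and 3 adjusted over the list alone). Their median was 0.10, with the replication clamp gene Pcna at 0.30 and Ccne1 at 0.52 (camera adjusted p = 2.34e-06, and 0.0956 with an estimated correlation). Mitochondrially encoded mRNAs rose in 8 of 12 cases and fell in 1 (10 and 1 adjusted over the list alone), with mt-Nd4 at 0.33 (camera adjusted p = 1.26e-06, and 0.351 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 25 cases (0 at least 2-fold) and fell in 5 (1 at least 2-fold), and the same 11 and 5 were counted adjusted over the list alone. Their median was 0.06 and their mean 0.05, with Ldha at 0.47 (camera adjusted p = 0.000184, and 0.351 with an estimated correlation). Of 39 ribosomal protein genes, 9 rose and 19 fell (9 and 21 adjusted over the list alone), and the list was not called (adjusted p = 0.0661). With the length trend removed, a step added after the trend was seen, the median was -0.07 and camera called the list downward (adjusted p = 0.000624). That call was lost with an estimated correlation (adjusted p = 0.0671).

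Among the largest changes in genes of 5 CPM or more, the chemokine receptor gene Ccr1 (ENSMUSG00000025804, chromosome 9, 123762161 to 123768729) rose from 4.05 ± 0.449 to 8.14 ± 0.0792 CPM (log2 fold change 1.00, SE 0.11, adjusted p = 2.73e-05), and Procr rose by 0.92. The mannose receptor gene Mrc1 fell by 1.31, Cd24a by 1.26, Cd93 by 1.06, Card14 by 1.06, Selenbp2 by 1.44 and Pianp by 1.91. Ppih, Tuba1a and Rps3a2 also stood among the 6 largest rises but have close copies and are uncertain. The test called 1878 genes higher and 2331 lower, 165 and 104 of them at least 2-fold, and by size alone 15 and 12 genes of 5 CPM or more were at least 2-fold higher and lower. Without preparation 2 of Mock, 1480 genes were lower.

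The third comparison asked which genes vesicles from uniSTING-treated 4T1 cells changed in the DC2.4 cells incubated with them, including genes that vesicle microRNAs might regulate. Interferon-stimulated genes rose strongly: 33 of 45 rose (18 at least 2-fold) and 0 fell, or 37 and 0 adjusted over the list alone. Rsad2 (ENSMUSG00000020641, chromosome 12, 26492745 to 26506451) rose from 0.810 ± 0.162 to 7.71 ± 0.954 CPM (log2 fold change 3.27, SE 0.24, adjusted p = 1.18e-06), and the antiviral synthetase gene Oas2 (ENSMUSG00000032690, chromosome 5, 120868398 to 120887918) from 1.32 ± 0.048 to 10.9 ± 0.313 CPM (log2 fold change 3.05, SE 0.20, adjusted p = 1.18e-06). Ifit1 rose by 3.02, Oasl2 by 2.92, Oas3 by 2.13 and Irf7 by 2.05. The list's median was 0.69, or 0.59 with 2 members that had a group at 0 set to their bound (camera adjusted p = 1.2e-36, and 0.000896 with an estimated correlation). Cxcl10 rose by 3.49, from 0.249 ± 0.352 to 2.50 ± 0.321 CPM (SE 0.61, adjusted p = 0.00167), on 34 and 58 counts against 7 and 0. That size rested on the EXOmock libraries: without preparation 2 of EXOmock the rise was 2.33 (adjusted p = 0.00678), and without preparation 1, which left the control at 0 counts, the fitted value was 8.69, which has no meaning as a size.

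Some MHC class I presentation genes rose with them, 8 of 22 higher and 2 lower (9 and 2 adjusted over the list alone), including H2-T23 at 0.59 and the light chain gene B2m at 0.25 (camera adjusted p = 1.3e-06, and 0.0382 with an estimated correlation). NF-kB targets stayed near 0, with 2 of 37 higher and 6 lower (3 and 7 adjusted over the list alone), a median of 0.00, a mean of 0.09 and a camera direction downward (adjusted p = 0.655), and Tnf fell by 0.28 (adjusted p = 0.0245). Ifnb1 had 2 summed counts against 0, and a change was not detectable at this depth. Tmem173 (0.19, adjusted p = 0.0958), Tbk1 (0.12, adjusted p = 0.185) and Irf3 (-0.17, adjusted p = 0.115) did not pass the test. Wnt2b, a Wnt ligand gene fixed beforehand (ENSMUSG00000027840, chromosome 3, 104852588 to 104869237), was below the count filter, with 1 summed count against 17 (ratio 0.0533, 95% counting interval 0.00128 to 0.34); with no filter its adjusted p was 0.00446. In the other comparisons Wnt2b had 10 against 11 and 17 against 20 summed counts. Il6 had 4 against 9 summed counts here (ratio 0.403, interval 0.0906 to 1.44), 0 against 1 in the libraries labelled DC2.4 given mRNA and 0 in all those labelled 4T1.

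The other lists called with vesicles moved by small amounts. Nuclear genes of oxidative phosphorylation rose in 10 of 22 cases and fell in 0 (17 and 1 adjusted over the list alone), with a median of 0.09, and ribosomal protein genes in 7 of 39 with 3 lower (11 and 3 adjusted over the list alone), with a median of 0.03. Camera called both lists (adjusted p = 6.34e-05 and 0.0114), and neither call held with an estimated correlation (adjusted p = 0.322 and 0.614). With the length trend removed, camera at the preset correlation called oxidative phosphorylation (adjusted p = 0.00504) but not ribosomal protein genes (adjusted p = 0.625). Id3, an inhibitor of helix-loop-helix transcription factors, rose by 2.39. The chemokine gene Ccl6 (ENSMUSG00000018927, chromosome 11, 83478708 to 83483913) fell from 141 ± 4.78 to 61.3 ± 0.954 CPM (log2 fold change -1.20, SE 0.10, adjusted p = 4.85e-06), the coagulation factor gene F5 by 1.08, Stfa3 by 1.07, Vasn by 0.96, Avil by 0.93 and the AP-1 gene Fosl1 by 0.85. Thbs1 fell by 0.56 from a high level (851 ± 6.11 to 578 ± 0.578 CPM) and the monocyte marker gene Cd14 by 0.39. Srp54b had the largest fitted rise (91 and 443 counts against 0 and 9) and has close copies, so it is uncertain, as are the Oas, Stfa and MHC class I genes. The test called 1183 genes higher and 1210 lower, 94 and 84 of them at least 2-fold. By size alone, 17 and 11 genes of 5 CPM or more were at least 2-fold higher and lower. Leaving out 1 of the 4 libraries at a time gave fewer calls in both directions each time, and DESeq2 called 743 lower.

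**Figure D3:**
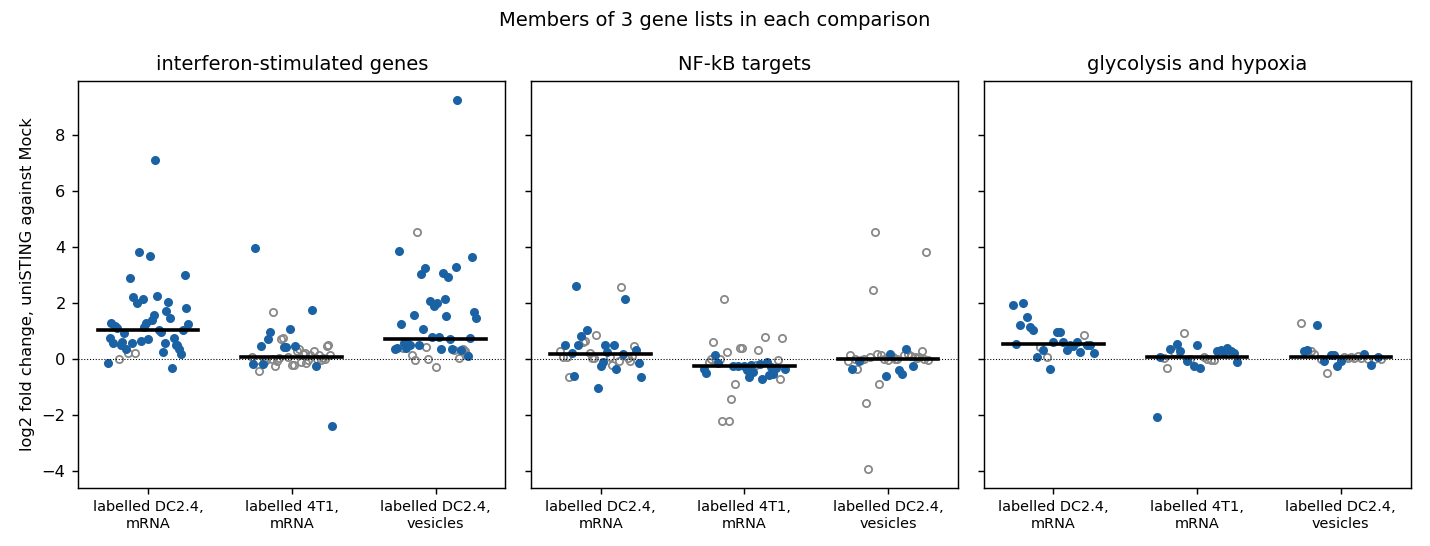
Fitted log2 fold change of each tested member (points; filled, past the threshold) and the median (line) of 3 gene lists in the 3 comparisons, groups as labelled; members with a group at 0 counts have fitted values that are not bounds. The interferon-stimulated medians were 1.01, 0.06 and 0.69, and the NF-kB medians 0.17, -0.25 and 0.00.

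The responses to uniSTING mRNA differed between the libraries labelled DC2.4 and those labelled 4T1 when the difference itself was tested. Of 45 interferon-stimulated genes, 28 responded more positively in the libraries labelled DC2.4 and 3 more negatively (median difference 0.74, camera adjusted p = 1.45e-07, and 0.00635 with an estimated correlation). Cholesterol synthesis (median difference 0.43), glycolysis and hypoxia (0.39) and ribosomal protein genes (0.34) also responded more positively there and cell cycle genes more negatively (-0.19), each also with an estimated correlation (adjusted p = 0.00635, 0.0413, 0.00635 and 0.0168). Genes matched to the ribosomal protein genes on mRNA length and mean count had medians of 0.28 under the DC2.4 label and 0.02 under the 4T1 label. Those matched to cholesterol synthesis genes had -0.06 and -0.03, and those matched to glycolysis and hypoxia genes 0.07 and 0.00. The list differences were not tested with the length trend removed. For NF-kB targets the median difference was 0.45, with 15 genes more positive and 2 more negative (camera adjusted p = 0.0112, lost with an estimated correlation, adjusted p = 0.101). The calls for oxidative phosphorylation (median difference 0.18), mitochondrially encoded mRNAs (-0.37) and MHC class I genes (0.06) were lost in the same way (adjusted p = 0.0514, 0.101 and 0.141). Over all genes, 2376 responded more positively and 2251 more negatively, 373 and 283 by at least 2-fold.

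Between mRNA and vesicles in the libraries labelled DC2.4, the interferon-stimulated genes as a list were not called different: 9 of 45 responded more positively to mRNA and 13 more negatively (median difference 0.11, camera adjusted p = 0.956 in the downward direction). Cholesterol synthesis (0.46), glycolysis and hypoxia (0.47) and ribosomal protein genes (0.27) responded more positively to mRNA, also with an estimated correlation (adjusted p = 0.0242, 0.0263 and 0.0209). Genes matched to the ribosomal protein genes on mRNA length and mean count had medians of 0.28 with mRNA and 0.03 with vesicles. Those matched to cholesterol synthesis genes had -0.06 and 0.00, and those matched to glycolysis and hypoxia genes 0.07 and 0.01. These list differences, too, were not tested with the length trend removed. Calls for oxidative phosphorylation (0.14), Wnt pathway (-0.22) and mitochondrially encoded genes (-0.26) were lost with one (adjusted p = 0.162, 0.255 and 0.274). Over all genes, 2272 responded more positively to mRNA and 2271 more negatively, 283 and 206 by at least 2-fold. These 2 experiments had their own controls, and their cells, judged by the markers, differed.

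With no fold minimum, calls in the same direction were shared more often than independent lists would share them, except between 4T1 and vesicles. The libraries labelled DC2.4 and 4T1 shared 784 higher genes against 391 expected (odds ratio 3.31, 2-sided Fisher's exact test, adjusted p = 3.96e-108) and 813 lower genes against 486 (2.4, adjusted p = 8.86e-66). Those given mRNA and those given vesicles under the DC2.4 label shared 433 higher genes against 246 (2.39, adjusted p = 1.53e-38) and 551 lower genes against 253 (3.64, adjusted p = 6.9e-90). Among genes at least 2-fold higher that pair shared 23 against 2.06 expected (15.5, adjusted p = 1.1e-17). There, the libraries labelled DC2.4 and 4T1 shared 15 against 3.61 (4.64, adjusted p = 7.67e-06). Among genes at least 2-fold lower, neither pair passed the threshold. Under the DC2.4 label mRNA and vesicles shared 2 against 1.23 (1.65, adjusted p = 0.418), and DC2.4 and 4T1 shared 2 against 1.52 (1.33, adjusted p = 0.705). With no fold minimum, the libraries labelled 4T1 and the vesicle-treated ones shared fewer higher genes than expected, 110 against 149 (0.691, adjusted p = 0.000432). They also shared fewer lower genes, 158 against 190 (0.793, adjusted p = 0.0135). By contrast, 420 genes were higher in the first and lower in the second against 153 expected (4.45, adjusted p = 2.12e-96). Genes lower in the first and higher in the second were not counted. At 2-fold, the libraries labelled 4T1 and the vesicle-treated ones shared 4 higher genes against 1.04 expected (4.03, adjusted p = 0.0309). These were Isg15, Rsad2, Cmpk2 and H2-T24, named after their values were seen. The pair also shared 5 lower genes against 0.588 expected (9.38, adjusted p = 0.000545). Another 9 genes were higher in the first and lower in the second against 0.933 expected (11.2, adjusted p = 9.57e-07). With no fold minimum, 496 genes were higher under the DC2.4 label with mRNA and lower under the 4T1 label, against 485 expected (1.03). Under the DC2.4 label, 251 were higher with mRNA and lower with vesicles against 252 (0.995). Expected counts covered all 14863 genes tested, including genes near 0 counts in some groups, so they and the odds ratios are rough. Log2 fold change fell with exonic length in each comparison, and its part in the sharing was not tested. Genes are not independent, so these exact p-values are too small.

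**Figure D4:**
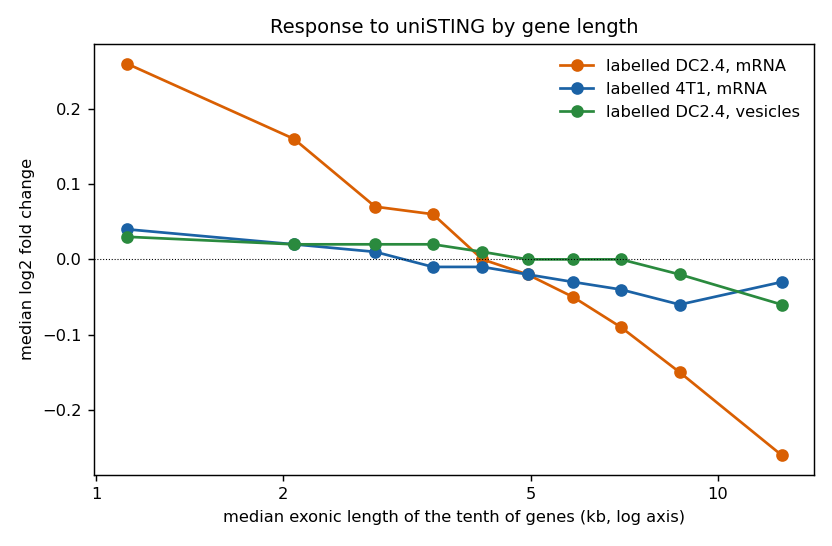
Median log2 fold change of genes in 10 equal bins of exonic length (kilobases, log axis) for the 3 comparisons, groups as labelled, over 10548 genes with a mean above 100 counts. The median ran from 0.26 to -0.26 in the libraries labelled DC2.4 given mRNA, and from 0.04 to -0.03 in those labelled 4T1.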

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

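The results below were picked because the response itself differed between 2 experiments when that difference was tested, by a planned rule, and all the technical tests that weigh them were chosen after the results were seen. Between the libraries labelled DC2.4 and those labelled 4T1, 2376 genes responded more positively to uniSTING mRNA under the first label and 2251 more negatively. The lists that differed, also with an estimated correlation, were interferon-stimulated genes (median difference 0.74), cholesterol synthesis (0.43), glycolysis and hypoxia (0.39), ribosomal protein genes (0.34) and cell cycle genes (-0.19). Among the genes with the smallest adjusted p were the ribosomal protein genes Rpl35 (1.06), Rpl37 (1.32) and Rpl38 (1.31), the ferritin gene Fth1 (0.43) and the unnamed locus AC122453.1 (1.66) in the positive direction, of which all but Fth1 are uncertain for their close copies. In the negative direction they were genes of very large proteins, the actin crosslinker gene Flna (-1.07), Plec (-1.71), the ubiquitin ligase gene Ubr4 (-1.54), Ahnak (-1.11), the dynein gene Dync1h1 (-1.44) and the myosin gene Myh9 (-0.94). The values given for these lists and genes were not adjusted for length. With the length trend removed, a step added after the trend was seen, 2231 genes responded more positively and 2234 more negatively. The list differences were not tested in that way. The fall of log2 fold change with exonic length was stronger under the DC2.4 label (Spearman's rho -0.42) than under the 4T1 label (-0.12).

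Between mRNA and vesicles under the DC2.4 label, 2272 genes responded more positively to mRNA and 2271 more negatively. The lists were cholesterol synthesis (0.46), glycolysis and hypoxia (0.47) and ribosomal protein genes (0.27). Among the genes were Ldha (0.70), Rpl35 (0.75), the early response gene Ier3 (1.30), Rpl19 (0.48) and Tpt1 (0.42), and, in the negative direction, Myh9 (-0.89), Plec (-1.20), the vimentin gene Vim (-0.54), Dync1h1 (-1.04), Lrp1 (-1.18) and the talin gene Tln1 (-0.81). The values of these lists and genes were not adjusted for length either. With the length trend removed, 2172 genes responded more positively to mRNA and 1929 more negatively. The correlation of exonic length with log2 fold change was -0.42 with mRNA and -0.13 with vesicles.

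The first pattern was the epithelial expression of the libraries labelled DC2.4 and given mRNA beside the leukocyte expression of those labelled 4T1. An exchange of the labels of the 2 cell lines between mRNA-treated libraries was tested by correlation with the vesicle-treated libraries: 8 of 8 libraries lay on the wrong side for their labels (0.684 to 0.691 for those labelled DC2.4, 0.981 to 0.984 for those labelled 4T1). The markers and the first principal component had already shown this grouping, so the correlation is no separate test of an exchange. The markers themselves argue against the cell line labels as given for all 8 libraries, and the correlations add no weight to that. Whether the epithelial libraries came from 4T1 cells, and at which step an exchange took place, was not tested and stays open. A mixture of both lines was argued against, since leukocyte markers in the libraries labelled DC2.4 given mRNA stood at a median of 0.101% of the vesicle-treated level. If the labels were exchanged, at whatever step, the direction of each response difference between the 2 lines would turn around. The contrast and overlaps of mRNA and vesicles under the DC2.4 label would then set different lines side by side. The libraries labelled 4T1 would then be the same line as the vesicle-treated ones.

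The second pattern was the closeness of the 2 libraries of each group and the transcripts of other tissues in preparation 1. Origin of both libraries in 1 culture or RNA stays open. In abundant genes, the highest variation beyond that of genes with intermediate counts was 0.62%, which understates the variation beyond counting. No spread between separate cultures was measured here to set beside it. Carry-over of material or reads among preparation 1 libraries was tested by epithelial markers in 6 of the 8 leukocyte-like libraries, leaving out the EXOmock pair, as 1 of its libraries was used to pick the markers; they were 5.19 times as high in preparation 1 (0.113 to 0.135% of the level in the epithelial ones) as in preparation 2 (0.0167 to 0.0365%). Its source stays open, since the transcripts of pancreas and lung in those libraries point to material of epithelial tissues, which would bring such markers too. Whether the 2 facts share a cause was not tested.

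The third pattern was the fall of long mRNAs and rise of short ones in the libraries labelled DC2.4 given uniSTING mRNA. Gene length as the account of the interferon-stimulated rise was argued against, since members lay 0.93 above genes matched on mRNA length and count, and the same held for glycolysis and hypoxia genes (0.49). For ribosomal protein genes the difference from matched genes was 0.04 and the question stays open. A difference in RNA integrity or library making also stays open: the highest correlation of length with the difference between libraries of a group was 0.02, but both libraries of a group could share 1 RNA. A biological effect of uniSTING on long mRNAs was not tested and stays open too.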

How the results depend on the processing

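Removal of the length trend and counts within 1 preparation were chosen after the result was seen, and the other alternatives before. At a minimum of 2-fold, the counts of higher and lower genes were 325 and 217 in the libraries labelled DC2.4 given mRNA, 165 and 104 in those labelled 4T1, 94 and 84 in the vesicle-treated ones, 373 and 283 for the difference between lines and 283 and 206 for mRNA against vesicles, lower because the threshold was stricter. DESeq2 called 743 genes lower with vesicles instead of 1210. Leaving out 1 library at a time, with fewer samples, gave 2302 to 2521 higher and 2434 to 2588 lower genes in the libraries labelled DC2.4 given mRNA, 1282 to 1459 and 1480 to 1807 in those labelled 4T1, and 603 to 769 and 689 to 764 with vesicles. It gave 1898 to 2185 and 1850 to 1975 for the difference between lines, and 1779 to 2016 and 1860 to 2031 for mRNA against vesicles. Interferon-stimulated medians stayed at 0.97 to 1.13, 0.05 to 0.11 and 0.62 to 0.76 in the 3 comparisons, and the NF-kB median at 0.06 to 0.17, -0.29 to -0.21 and 0.00. For the libraries labelled DC2.4 given mRNA it was also 0.09, instead of 0.17, with the stricter filter and with only the libraries compared, and it was called under none of these. Under the 4T1 label that list kept its median of -0.25 but lost its call with an estimated correlation (adjusted p = 0.0956). The NF-kB median with vesicles, 0.00, was -0.01 with the stricter filter of 1 CPM in 4 libraries, -0.01 with only the libraries compared and 0.01 with the length trend removed. At 2-fold, the overlap odds ratio of 4T1 and vesicles turned from 0.691 to 4.03 for higher and from 0.793 to 9.38 for lower genes, and that of genes higher with mRNA and lower with vesicles under the DC2.4 label from 0.995 to 2.86. The ratios for shared lower genes weakened to 1.33 (DC2.4 and 4T1) and 1.65 (DC2.4 mRNA and vesicles). Both lost their calls (Fisher's exact test, adjusted p = 0.705 and 0.418). By size alone, genes of 5 CPM or more at least 2-fold higher and lower under the DC2.4 label with mRNA numbered 98 and 53 in preparation 1 and 79 and 52 in preparation 2, against 75 and 40 with both summed; under the 4T1 label they numbered 18 and 22, 22 and 18, and 15 and 12, and with vesicles 29 and 25, 23 and 15, and 17 and 11. Where the wording above gives no reason, the cause was not tested.

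Genes near 0 changed sign. With the length trend removed, Tmem173 went from 0.09 to 0.00 and Irf3 from 0.04 to -0.01 in the libraries labelled DC2.4 given mRNA, and Tbk1 from -0.01 to 0.00 in those labelled 4T1. Tbk1 there was 0.00 with only the libraries compared and 0.01 with upper-quartile factors. Leaving out 1 library at a time, Irf3 ran from -0.01 to 0.09 in the libraries labelled DC2.4, and in those labelled 4T1 Cxcl10 ran from -0.56 to 0.18, Ifit1 from -0.41 to 0.21, Tmem173 from -0.03 to 0.09 and Tbk1 from -0.05 to 0.05; the cause was not tested. Over the named genes and the lists not given above, with no 2-fold setting, 1974 of 2056 alternatives were the same, 66 weaker, 2 stronger and 14 reversed.

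The preparation number was fitted as a block: it gave 3421 higher and 3367 lower genes in the libraries labelled DC2.4 given mRNA, 2148 and 2683 in those labelled 4T1 and 1444 and 1477 with vesicles. In the pairing check, deviations of the preparations correlated at 0.26 to 0.51 across pairs of groups over 11378 genes, so libraries with the same number deviated together, a hint from the data that they were handled together. The labels do not say that a number marks a shared day or batch, and each comparison holds 2 such pairs, so the planned fit without the block was kept.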

Other observations

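The list tests here were planned, and the transcripts of other tissues were chosen after the result was seen. The components of the STING pathway went both ways in the libraries labelled DC2.4 given mRNA: 5 of 17 rose and 5 fell, also adjusted over the list alone, with the autophagy receptor gene Sqstm1 at 0.24, the ubiquitin ligase gene Trim56 at -0.55 and the kinase gene Ulk1 at -0.43 (median 0.07, mean -0.04, camera adjusted p = 0.841). In those labelled 4T1, 2 rose and 4 fell, also adjusted over the list alone, with Sqstm1 at -0.25 and the kinase gene Ikbke at -0.46 (median 0.01, mean 0.17, camera direction downward, adjusted p = 0.523). With vesicles, 2 rose and 2 fell (2 and 3 adjusted over the list alone), with the DNA sensor gene Ifi204 at 1.54 and Sqstm1 at -0.10 (adjusted p = 0.635). Genes of the unfolded protein and integrated stress response split evenly with mRNA under the DC2.4 label, 13 of 30 higher and 13 lower (14 and 13 adjusted over the list alone), with the amino acid transporter gene Slc7a5 falling from 727 ± 0.190 to 436 ± 3.56 CPM (log2 fold change -0.72) and the stress factor gene Atf3 rising by 0.76 (median 0.03, camera direction downward, adjusted p = 0.452). With the length trend removed, a step added after the trend was seen, the median was -0.05 and camera called the list (adjusted p = 0.0104), a call lost with an estimated correlation (adjusted p = 0.0593). That list had 6 higher and 7 lower under the 4T1 label (7 and 8 adjusted over the list alone, adjusted p = 0.973) and 3 and 8 with vesicles (the same adjusted over the list alone, adjusted p = 0.128), where Slc7a5 fell by 0.26 and the chaperone gene Hspa5 by 0.14. With vesicles and the length trend removed, camera called the list downward (adjusted p = 0.016), a call lost with an estimated correlation (adjusted p = 0.112).

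Cell death genes rose in 10 of 25 cases and fell in 4 with mRNA under the DC2.4 label (11 and 4 adjusted over the list alone), with the necroptosis gene Mlkl at 0.39 and the pro-apoptotic gene Bcl2l11 at -0.43, and the list was not called (adjusted p = 0.159). It had 5 higher and 5 lower under the 4T1 label (adjusted p = 0.973) and 3 and 1 with vesicles (median 0.00, mean -0.11, camera direction upward, adjusted p = 0.886). Of 19 p53 targets, 6 rose and 2 fell under the DC2.4 label, among them Mdm2 at 0.49 and Sesn2 at -0.69 (adjusted p = 0.297), 2 and 6 under the 4T1 label (adjusted p = 0.235) and 2 and 3 with vesicles (4 and 4 adjusted over the list alone, adjusted p = 0.966). Dendritic cell maturation genes had 6 higher and 2 lower of 16 under the DC2.4 label, including the co-stimulatory ligand gene Tnfsf9 at 0.96 (adjusted p = 0.854), 1 and 2 under the 4T1 label, where Cd83 fell by 0.62 and Relb by 0.73 (adjusted p = 0.973), and 3 and 1 with vesicles, where Cd83 rose by 0.43 (adjusted p = 0.204). Interferon-induced GTPases rose in 5, 2 and 1 of 14 cases and fell in 0 (5, 1 and 1 adjusted over the list alone), with Irgm2 at 1.48 and Igtp at 1.43 under the DC2.4 label and Irgm1 at 0.78 with vesicles (adjusted p = 0.0731, 0.444 and 0.0981; median with vesicles 0.51, or 0.24 with members at their bound). Of 9 MHC class II genes, 1 rose and 1 fell under the DC2.4 label (1 and 0 adjusted over the list alone), Cd74 at 0.83 and Ifi30 at -0.15, 1 rose and 1 fell under the 4T1 label, Cd74 at 0.48 and Ctss at -0.23, and 1 rose and 0 fell with vesicles, Ifi30 at 0.25 (adjusted p = 0.591, 0.973 and 0.137).

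Other lists stayed uncalled. Under the 4T1 label these were cholesterol synthesis (7 higher and 2 lower, adjusted p = 0.259), oxidative phosphorylation (6 and 8, adjusted p = 0.973), MHC class I (5 and 3, adjusted p = 0.506), Wnt pathway (1 and 4, adjusted p = 0.235), TGF-beta and matrix (3 and 4, median -0.09, mean 0.26, adjusted p = 0.94), epithelial markers (1 and 0, adjusted p = 0.639) and histones (2 and 1, adjusted p = 0.909). With vesicles they were cholesterol synthesis (6 and 1, adjusted p = 0.137), glycolysis and hypoxia (7 and 4, adjusted p = 0.128), cell cycle (5 and 9, adjusted p = 0.383), Wnt pathway (4 and 1, adjusted p = 0.322), TGF-beta and matrix (0 and 1, median -0.01, mean 0.05, adjusted p = 0.655), leukocyte markers (5 and 4, adjusted p = 0.789), epithelial markers (0 and 0, adjusted p = 0.947), mitochondrially encoded mRNAs (1 and 0, adjusted p = 0.137) and histones (1 and 0, median 0.00, mean -0.32, adjusted p = 0.635). None of the 3 tested lymphocyte markers passed in any comparison (adjusted p = 0.968, 0.973 and 0.655), and their medians were 0.00 with members at their bound.

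Further transcripts of other tissues stood at 0 in each preparation 2 library and above 0 in each of preparation 1: the glucagon gene Gcg at 15 to 268 counts, the amylin gene Iapp at 26 to 358, the airway gene Scgb1a1 at 169 to 397, the surfactant gene Sftpa1 at 84 to 142 and the globin gene Hbb-bs at 61 to 100.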
